A study of Homo sapiens with 12 samples.

How the data were processed

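The series profiled human mesenchymal stem cells (hMSC), the stromal progenitors that can form bone, cartilage and fat cells, labelled with GFP according to the series design text. Cells were kept in osteogenic medium for 8 days either on coated microcarrier beads in a rotating wall vessel (RWV, a slowly rotating bioreactor that keeps beads suspended at low shear) or as monolayers. The growth surface carried either collagen I or hMatrix, an extracellular matrix made by hMSC that had been driven towards bone. Each of the 4 combinations had 3 cultures, called biological triplicates by the submitters, and each culture gave 1 array. Per the labels, cultures were started with equal cell numbers on 50 cm2, and 200 ng of total RNA with an integrity score of 10 was labelled with biotin. The RWV cultures had 48 h of equilibration before osteogenic medium. No such step is stated for the monolayers. The number of donors and the slide of each array are not given in the sources used here.

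The labelled RNA was hybridised to Illumina HumanHT-12 v4 bead arrays, which carry long oligonucleotide probes on beads. The authors scanned the arrays and summarised each probe in GenomeStudio version 3. The values were deposited as intensity on a linear scale, quantile normalized by the authors between the 12 arrays, with a detection p value (a p_value against the negative controls of the array) per probe and array. Per the file headers, the table was made with module version 1.9.0 in an analysis named as having no background subtraction. The series design text says that background correction was done. The values bear out the header, since the lowest value is 92.6 and undetected probes lie near 113 units. All folds below therefore contain background and are understated, most of all for dim genes. The deposited series value table held the same intensity values, with 0 differences.

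The table held 47321 probes, 92 of them control probes. The other 47229 were matched by Entrez identifier to current gene symbols in the reference annotation, and 35671 found a match. This also restored 54 symbols that a spreadsheet had turned into dates. Several genes stand in the files under older symbols, among them CCN2 as CTGF, MAP3K7CL as C21orf7, P3H2 as LEPREL1 and RGCC as C13orf15. XIST and Y-linked genes were left out of all tables. Chromosomes are those the deposited table gives. Probe coordinates are not printed, because the table names no genome build.

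A probe counted as measured when its detection p was under 0.01 on all 3 arrays of at least 1 group. This left 16888 probes for 12924 genes. Each gene was represented by its measured probe of highest mean log2 value. Values under 16 were to be raised to 16 before taking log2, and none were that low. One linear model over all 12 arrays and 4 groups was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 8 residual degrees of freedom, 5.378 prior degrees of freedom). The 4 groups share 1 estimate of the spread per gene. Leaving out an array outside a comparison therefore changes its adjusted p values and not its log2 changes. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 4 comparisons of 2 groups were hMatrix against collagen I in the RWV and in monolayer, and the RWV against monolayer on each coating. The interaction asked whether the hMatrix effect differed between the RWV and monolayer. All tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 12924 genes. Genes with adjusted p under 0.05 are called higher or lower, and "rose" and "fell" are used of these alone. Every adjusted p of a gene is limma's.

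A set of 33 gene lists of pathways and of markers of other cell types was fixed before the data were examined. The 32 lists with at least 5 measured genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 160 tests of 32 lists in 5 contrasts. The endothelial list had too few measured members. Camera with an estimated correlation and fry were run beside it. Over all contrasts, 52 list tests passed with the preset correlation and 1 of these with an estimated correlation, that of the cell cycle list between the RWV and monolayer on collagen I. The adjusted p with an estimated correlation stands beside the result of each list that passed. In none of the 52 did the median, the mean and the test differ in sign.

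The rule for named genes was also fixed before the data were examined. It takes the largest rises and falls among genes past the threshold whose 3 arrays of one group all lay beyond the 3 of the other and that were detected on all 3 arrays of the higher group. It adds a set of focus genes of osteogenesis, matrix and signalling wherever measured, and up to 4 members of each list described, the 2 risen and 2 fallen with the smallest adjusted p. The interaction has its 5 largest positive and negative values. The rule allowed at least 5 genes per direction, and the number of 6 was chosen after the values were seen. Of the focus genes, SP7 and IBSP were not measured. Some list members that the rule takes are not named in the text. Outside the rule, HERPUD1, MUC1, ELF3, KRT16, KRT17, KRT19, IFI6, CDC42BPB, PPDPF and NACC1 are named after their values were seen, and ARRDC4 for a test written before its values were looked at. Where the dimmer group was not detected on any array, the fold is computed against the lowest detected intensity of each array (131.5 to 136.8) and given as "at least".

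The fit was tested on simulated data drawn from the arrays' own gene means and spreads, with 50 genes per size of change. At a log2 change of 0.50, 47 of 50 genes were called between coatings in the RWV, 41 in monolayer, 46 between culture systems on collagen I, 44 on hMatrix and 20 in the interaction. At a log2 change of 1, 49 of 50 were called in the interaction and all 50 elsewhere. Between 6 and 11 of the unchanged genes were called in each contrast. The simulation changed few genes and drew each array independently. In the data, 25.1% and 27.1% of genes passed between coatings in the RWV and in monolayer. Deviations of some arrays from their group means were also correlated (0.576 for monolayer hMatrix array 2 with monolayer collagen I array 3). The simulated rates therefore need not hold for the data. For arrays, the number per group limits the precision: the median standard error of a log2 change was 0.09 between groups and 0.12 in the interaction.

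The alternatives covered the floor before log2, an offset of 50, detection filters, normalization, subtraction of each array's lowest value, the mean of a gene's probes, a trended robust prior, array weights, a fit on only the arrays compared, stricter calling rules, the rule of the series design text (a fold of group means of at least 2 with SD at most 0.25 of the mean), and leaving out each array in turn. A normexp background correction from the detection p values, and a fit without monolayer hMatrix array 2 and monolayer collagen I array 3, were chosen after seeing the data, as was the estimated correlation with arrays left out. A block for the slide was planned and was not run, since no file names the slide.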

Results

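The 12 arrays measured transcripts in hMSC after 8 days of osteogenic culture, with 3 cultures on hMatrix in the RWV, 3 on collagen I in the RWV, 3 on hMatrix in monolayer and 3 on collagen I in monolayer. Between 16866 and 18215 probes per array were detected at a detection p under 0.01. All arrays shared one distribution up to a highest value of 32687.7 units, since the values were quantile normalized. The 92 control probes were not tested, and 0 of them were detected on all arrays. Correlations of log2 intensity between arrays, taken across genes, which are not independent replicates, lay between 0.9895 and 0.9965 within groups and between 0.9664 and 0.9902 between groups. The first principal component carried 44.84% of the variance and separated the coatings. The second carried 24.84% and separated the RWV from monolayer, with monolayer hMatrix array 2 (score −20.9) and monolayer collagen I array 3 (score −18.8) farthest along it.

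**Figure D1:**
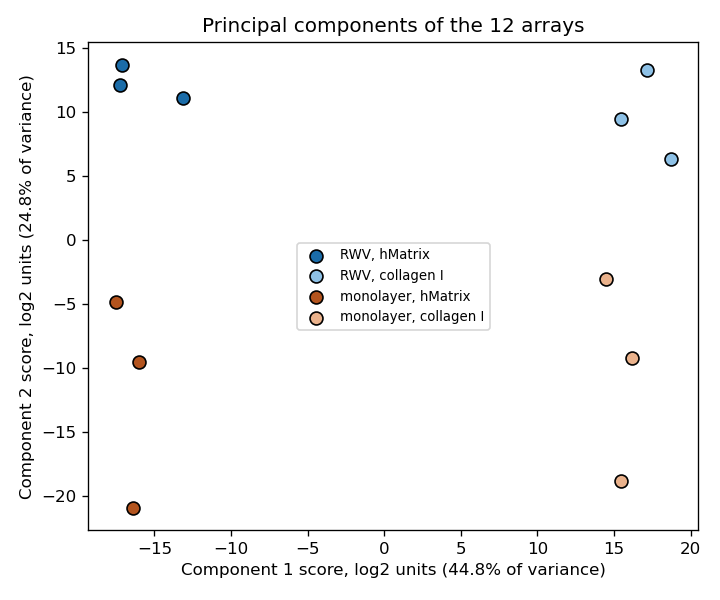
Scores of the 12 arrays on the first and second principal components of log2 intensity, in log2 units, with the share of variance on each axis and 1 point per array coloured by group. All hMatrix arrays lie at negative and all collagen I arrays at positive scores of component 1, and the RWV arrays lie above the monolayer arrays on component 2.

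The first comparison asked how hMatrix changed transcription relative to collagen I on beads in the RWV, the contrast the series was designed around. CYP1B1 on chromosome 2, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 9.73-fold, from 974.0 ± 154 to 9496 ± 1620 intensity units (SD, n = 3; log2 change 3.28, SE 0.13, adjusted p = 1.62e-09). DDIT4L on chromosome 4, an inhibitor of mTOR signalling, rose 8.84-fold (log2 change 3.14, SE 0.14, adjusted p = 6.19e-09). The next largest rises were 5.93-fold for CHI3L1 (chromosome 1), a secreted chitinase-like glycoprotein, 5.74-fold for HAS3 (chromosome 16), a hyaluronan synthase, 5.68-fold for COLEC12 (chromosome 18), a scavenger receptor, and 5.02-fold for HMOX1 (chromosome 22), heme oxygenase 1. On the deposited values, the largest fall was that of IGFBP2 on chromosome 2, a binding protein of insulin-like growth factors, at 5.63-fold, from 1804 ± 130 to 320.5 ± 18.8 units (log2 change −2.49, SE 0.09, adjusted p = 1.26e-09). ALPL on chromosome 1, the alkaline phosphatase of bone mineralisation, fell 4.62-fold, from 1488 ± 185 to 321.0 ± 21.3 units (log2 change −2.21, SE 0.18, adjusted p = 1.63e-06). MAP3K7CL (chromosome 21) fell 4.15-fold, OXTR (chromosome 3), the oxytocin receptor, 4.07-fold, KCTD20 (chromosome 6) 3.96-fold and DBNDD2 (chromosome 20) 3.69-fold. By the rule for named genes, all 3 hMatrix arrays of each of these 12 genes lay beyond all 3 collagen I arrays.

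Of the genes of osteoblast differentiation, 7 of 12 measured members rose on hMatrix in the RWV and 1 fell (adjusted over the list alone, 7 and 1). BMP4, a bone morphogenetic protein, rose 1.92-fold (log2 change 0.94, adjusted p = 2.49e-05) and DLX5, a homeobox factor of osteoblasts, 1.85-fold (log2 change 0.89, adjusted p = 0.00024). RUNX2, the master transcription factor of the osteoblast lineage, rose by 0.55 on the log2 scale (adjusted p = 0.000272, passed by 1 of its 2 measured probes). BMP2 rose at least 1.14-fold, being undetected on collagen I. SPP1, which encodes the bone matrix protein osteopontin, rose by 0.33 (adjusted p = 0.0127, passed by 1 of 2 probes), and its adjusted p was 0.0568 without RWV hMatrix array 1 and 0.0551 without array 2. The single fallen member was ALPL. BGLAP, osteocalcin, was close to background on both coatings, at 154.7 ± 3.87 and 140.6 ± 17.0 units (adjusted p = 0.255). Camera placed the list above other genes (adjusted p = 0.0013, or adjusted p = 0.0813 with an estimated correlation). TNFRSF11B, the decoy receptor osteoprotegerin that blocks osteoclast formation, fell 3.26-fold (log2 change −1.71, SE 0.11, adjusted p = 1.69e-07), and IL6 fell by 0.93 on the log2 scale (adjusted p = 3.35e-05).

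Genes of BMP and TGF-beta signalling moved both ways in the RWV. On hMatrix, 10 of 21 measured members rose and 4 fell (adjusted over the list alone, 10 and 4; adjusted p = 0.00247, or adjusted p = 0.177 with an estimated correlation). ID2, an inhibitor of basic helix-loop-helix factors and a BMP target, rose 3.46-fold and the ligand TGFB3 2.61-fold, while the activin antagonist FST fell 1.75-fold. Of 25 measured targets of YAP and SRF, which respond to cell tension, 10 fell and 0 rose (adjusted over the list alone, 11 and 0; adjusted p = 5.13e-05, or adjusted p = 0.132 with an estimated correlation). Calponin CNN1 fell 3.59-fold and ANKRD1 2.40-fold, and CCN2, a connective tissue growth factor, fell by 0.97 on the log2 scale (adjusted p = 1.17e-05). Markers of smooth muscle cells and pericytes, 4 of whose measured members the YAP and SRF list also holds, fell in 6 of 10 measured cases and rose in 2 (adjusted over the list alone, 7 and 2; adjusted p = 0.0118, or adjusted p = 0.132 with an estimated correlation). ACTG2, smooth muscle gamma actin, fell 2.63-fold. KCNJ8 and PDGFRB, which mark pericytes, rose 1.48-fold and 1.57-fold. ACTA2, smooth muscle alpha actin, had a log2 change of −0.21 (adjusted p = 0.136).

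Proliferation genes were lower on hMatrix in the RWV, where 25 of 29 measured cell cycle genes fell and 1 rose (adjusted over the list alone, 28 and 1). The mitotic kinase AURKA fell by 0.87 and the mitotic kinesin KIF20A by 0.77 on the log2 scale (adjusted p = 1.59e-06 and 1.53e-05). MKI67 fell at least 1.08-fold, being undetected on hMatrix. PCNA, the sliding clamp of DNA replication, rose by 0.38 (adjusted p = 0.00969), and its adjusted p was 0.0519 without RWV collagen I array 3. Camera gave adjusted p = 7.89e-14 for the list, or adjusted p = 0.0548 with an estimated correlation. Of the lysosomal and autophagy genes, 12 of 23 measured members rose and 0 fell (adjusted over the list alone, 14 and 0; adjusted p = 2e-06, or adjusted p = 0.0548 with an estimated correlation). LAMP2, a lysosomal membrane protein, rose 1.5-fold. Of the HIF target and glycolysis genes, 13 of 27 rose and 2 fell (adjusted over the list alone, 15 and 4; adjusted p = 0.000656, or adjusted p = 0.318 with an estimated correlation). DDIT4, which restrains mTOR under hypoxia, rose 3.31-fold and NDRG1 3.83-fold. RWV hMatrix array 1 lay below the other 2 on this list, with a median deviation of −0.274 against 0.106 on each, and without it the log2 changes of DDIT4 and NDRG1 were 2.00 and 2.24 against 1.73 and 1.94. VEGFA, the best known HIF target, had a log2 change of 0.65 with an SE of 0.26 (adjusted p = 0.0823), and passed without monolayer collagen I array 2 (adjusted p = 0.0335) or array 3 (adjusted p = 0.0362) and in a fit of the RWV arrays alone (adjusted p = 0.00411). The monolayer arrays enter this result only through the shared spread.

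Among matrix genes in the RWV, COL12A1, a fibril-associated collagen, rose 2.92-fold on hMatrix (log2 change 1.55, SE 0.13, adjusted p = 2.22e-06). The fibrillar collagen gene COL3A1 rose by 0.73 and COL6A3 by 0.34 on the log2 scale (adjusted p = 0.000122 and 0.00886), the chemokine CXCL12 rose by 0.74 (adjusted p = 7.38e-05), and POSTN, periostin, fell by 0.50 (adjusted p = 0.00952). COL1A1 had a log2 change of 0.11 (adjusted p = 0.224) at 28127 ± 583 and 26132 ± 1210 units, close to the ceiling of the arrays. FN1 (0.04), DKK1 (−0.22), PPARG (−0.22) and SOX9 (0.28) also missed the threshold, with adjusted p values of 0.882, 0.247, 0.0954 and 0.0867. PPARG passed without RWV collagen I array 3 (adjusted p = 0.0352) and SOX9 without monolayer collagen I array 3 (adjusted p = 0.0358). Of 7 measured epithelial markers, which are keratins, MUC1 and ELF3, 5 fell on hMatrix and 0 rose (adjusted over the list alone, 6 and 0; adjusted p = 5.16e-05, or adjusted p = 0.0548 with an estimated correlation). KRT7 fell 3.54-fold, from 577.8 ± 29.9 to 163.4 ± 5.71 units, and KRT14 at least 2.67-fold, being undetected on hMatrix. Of 8 measured markers of macrophages and blood cells, 2 rose and 1 fell (adjusted p = 0.779).

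In total, 1593 genes were higher and 1654 lower on hMatrix than on collagen I in the RWV, 25.1% of the 12924 tested. A change of at least 2-fold was seen in 111 of the higher and 80 of the lower genes, and the median size among called genes was 0.40 on the log2 scale. Of the 32 lists tested, 14 passed. With a normexp background correction, chosen after seeing the data, the counts at 2-fold were 270 and 239. The order of the dim genes changed with it: DDIT4L rose 19.6-fold and CYP1B1 10.7-fold. KRT14, undetected on hMatrix, fell 12-fold, more than IGFBP2 (7.66-fold).

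**Figure D2:**
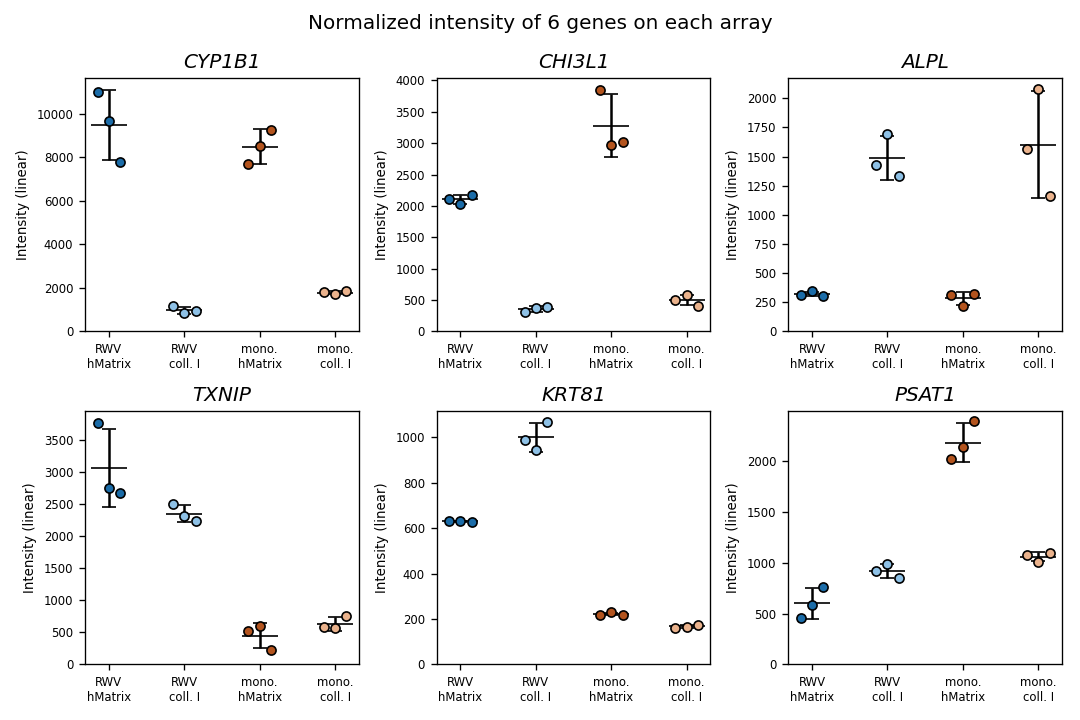
Normalized intensity (linear scale, axes from 0) of CYP1B1, CHI3L1, ALPL, TXNIP, KRT81 and PSAT1, with 1 point per array, a bar at the mean and whiskers of 1 SD of 3 arrays. CYP1B1 and CHI3L1 are higher and ALPL is lower on hMatrix in both culture systems, TXNIP and KRT81 are higher in the RWV on both coatings, and PSAT1 is highest in monolayer on hMatrix (2181 ± 190 units).

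The same coatings were then compared in monolayer, to see what hMatrix changed without beads and rotation. DDIT4L rose 7.60-fold on hMatrix, from 137.4 ± 3 to 1062 ± 232 units (log2 change 2.93, SE 0.14, adjusted p = 2.03e-08), CHI3L1 6.62-fold and CYP1B1 4.74-fold. DDIT4, the paralogue of DDIT4L, rose 4.71-fold, RGCC (chromosome 13), a regulator of the cell cycle, 4.64-fold and PTGDS (chromosome 9), prostaglandin D2 synthase, 4.38-fold. ALPL showed the largest fall, 5.58-fold, from 1602 ± 460 to 283.1 ± 56.8 units (log2 change −2.48, SE 0.18, adjusted p = 7.94e-07). SCUBE3 (chromosome 6), a secreted glycoprotein, fell 4.88-fold, P3H2 (chromosome 3), a collagen prolyl 3-hydroxylase, 4.87-fold, MAP3K7CL and the matrix protein gene ABI3BP (chromosome 3) 3.62-fold each and IGFBP2 3.42-fold.

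Of 25 measured targets of YAP and SRF, 10 fell on hMatrix in monolayer and 0 rose (adjusted over the list alone, 10 and 0; adjusted p = 0.000317, or adjusted p = 0.164 with an estimated correlation), among them the receptor tyrosine kinase gene AXL, which fell 1.75-fold, and the non-muscle myosin gene MYH9, 1.41-fold. Of 23 integrin and focal adhesion genes, 12 fell and 2 rose (adjusted over the list alone, 14 and 3; adjusted p = 0.00305, or adjusted p = 0.132 with an estimated correlation). ITGA3, a laminin-binding integrin, fell 2.37-fold and the proteoglycan gene SDC4 1.83-fold, while its relative SDC1 rose 2.68-fold and ITGB5 1.25-fold. Of 17 basement membrane genes, 8 fell and 1 rose (adjusted over the list alone, 10 and 1; adjusted p = 0.00275, or adjusted p = 0.21 with an estimated correlation). COL4A1, the basement membrane collagen, fell 1.77-fold and LAMC1, the laminin gamma 1 chain, 1.57-fold, and LAMA2 rose 1.25-fold from a level detected on 2 of 3 arrays. CCN2 fell by 0.45 on the log2 scale (adjusted p = 0.0049), and ACTA2 had a log2 change of −0.05 (adjusted p = 0.75).

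Cell cycle genes were lower on hMatrix in monolayer as well, with 17 of 29 fallen and 1 risen (adjusted over the list alone, 21 and 1; adjusted p = 2.76e-07, or adjusted p = 0.132 with an estimated correlation). TOP2A, the mitotic topoisomerase, fell 1.9-fold and the thymidine kinase gene TK1 1.77-fold, and PCNA rose 1.35-fold. MKI67 was undetected on both coatings. Of the lysosomal and autophagy genes 11 of 23 rose and 1 fell (adjusted over the list alone, 14 and 1; adjusted p = 7.73e-06, or adjusted p = 0.0548 with an estimated correlation). NPC2, a lysosomal cholesterol carrier, rose 1.69-fold, and the cathepsin gene CTSZ fell 1.56-fold. HIF targets and glycolysis genes rose in 15 of 27 cases and fell in 1 (adjusted over the list alone, 16 and 2; adjusted p = 0.000244, or adjusted p = 0.308 with an estimated correlation), with NDRG1 up 3.09-fold. VEGFA had a log2 change of 0.12 (adjusted p = 0.775). The unfolded protein and amino acid response moved upward, with 16 of 27 genes risen and 3 fallen (adjusted over the list alone, 16 and 3; adjusted p = 0.000822, or adjusted p = 0.221 with an estimated correlation). The serine synthesis genes PSAT1 and PSPH rose 2.05-fold and 1.80-fold, while the endoplasmic reticulum chaperone genes HSPA5 and HSP90B1 fell 1.67-fold and 1.44-fold.

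Of the osteoblast genes in monolayer, 6 of 12 rose on hMatrix and 1, ALPL, fell (adjusted over the list alone, 6 and 1; adjusted p = 0.0474, or adjusted p = 0.18 with an estimated correlation). This call was lost without monolayer collagen I array 2 (adjusted p = 0.06) or 3 (adjusted p = 0.0833), monolayer hMatrix array 2 (adjusted p = 0.0936), RWV collagen I array 1 (adjusted p = 0.0519) or RWV hMatrix array 1 (adjusted p = 0.0522). BMP4 rose 2.46-fold, RUNX2 by 0.42 on the log2 scale (adjusted p = 0.00207, passed by 1 of its 2 probes), BMP2 at least 1.11-fold and COL10A1, a collagen of hypertrophic cartilage, at least 1.19-fold. SPP1 rose by 0.32 (adjusted p = 0.0145), and its adjusted p was 0.05 without monolayer hMatrix array 2 and 0.0538 without monolayer collagen I array 3. TNFRSF11B fell by 0.77, IL6 by 0.79, the Wnt antagonist DKK1 by 0.57 and PPARG, the adipogenic nuclear receptor, by 0.69 (adjusted p = 0.000282, 0.000171, 0.00525 and 0.000115). COL12A1 rose by 1.09 and CXCL12 by 0.55 (adjusted p = 7.19e-05 and 0.00099). Of the other matrix genes, COL1A1 (−0.17), COL3A1 (−0.01), COL6A3 (−0.09), POSTN (0.11) and FN1 (−0.36) missed the threshold, with adjusted p values of 0.0558, 0.941, 0.446, 0.544 and 0.0724, as did BGLAP (0.04, adjusted p = 0.783) and SOX9 (−0.28, adjusted p = 0.0757). FN1 passed without monolayer hMatrix array 2 (adjusted p = 0.00367), and COL1A1 passed, as lower, without a detection filter (adjusted p = 0.024) or with its probes averaged (adjusted p = 0.0366). Tested probe by probe, 1 of the 3 measured probes of FN1 passed as lower.

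In total, 1651 genes were higher and 1855 lower on hMatrix in monolayer, 27.1% of those tested, with 88 and 65 of them changed at least 2-fold (219 and 237 with the normexp correction). With that correction DDIT4L rose 23.7-fold, RGCC 11.6-fold, CHI3L1 8.03-fold, PTGDS 7.76-fold, COMP 5.86-fold, DDIT4 5.25-fold and CYP1B1 4.96-fold. The count of higher genes was 1098 when only the 6 monolayer arrays were fitted. Of 32 lists, 13 passed.

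The third comparison asked how transcription in the RWV differed from monolayer when both carried collagen I. The 2 culture systems differ in beads, in rotation and in the 48 h of equilibration stated for the RWV alone. In this comparison and the next these factors cannot be told apart. KRT81 (chromosome 12), a keratin of hair, rose 5.98-fold in the RWV, from 167.1 ± 6 to 1000 ± 63.7 units (log2 change 2.58, SE 0.07, adjusted p = 3.84e-11). TXNIP (chromosome 1), the thioredoxin-interacting protein gene that glucose induces, rose 3.74-fold (log2 change 1.9, SE 0.27, adjusted p = 0.00054). CRIP1 (chromosome 14) rose 3.55-fold, CDC20 (chromosome 1), the activator of the anaphase-promoting complex, 3.27-fold and KRT34 (chromosome 17), another hair keratin gene, 3.19-fold. KRT14 (chromosome 17), a keratin of basal epidermis, rose at least 2.66-fold from undetected. On the deposited values, the largest fall was 2.69-fold for ITGA2 (chromosome 5), a collagen-binding integrin, from 1168 ± 83.3 to 434.2 ± 20.1 units (log2 change −1.43, SE 0.12, adjusted p = 1.57e-05). IFI44L (chromosome 1), an interferon-stimulated gene, fell 2.50-fold, LRRC17 (chromosome 7) 2.44-fold, MGP (chromosome 12), an inhibitor of calcification, 2.22-fold, the annexin gene ANXA10 (chromosome 4) 2.15-fold and the stress cytokine gene GDF15 (chromosome 19) 2.11-fold.

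Proliferation genes were higher in the RWV on collagen I, where 27 of 29 cell cycle genes rose and 0 fell (adjusted over the list alone, 28 and 0; adjusted p = 2.73e-29, and adjusted p = 0.0281 with an estimated correlation). KIF20A rose 2.35-fold and AURKA 1.99-fold. MKI67 rose at least 1.08-fold (adjusted p = 0.0155), and missed the threshold without RWV collagen I array 1 (adjusted p = 0.0682) or monolayer collagen I array 1 (adjusted p = 0.0527). Of 7 epithelial markers 4 rose and 0 fell (adjusted over the list alone, 4 and 0; adjusted p = 0.000431, or adjusted p = 0.0687 with an estimated correlation), KRT7 by 2.48-fold. Of 24 fibrillar collagen and processing genes, 4 fell and 1 rose (adjusted over the list alone, 6 and 1; adjusted p = 0.00719, or adjusted p = 0.21 with an estimated correlation). COL3A1 fell 1.44-fold and the minor fibrillar collagen gene COL11A1 rose 1.36-fold, though COL11A1 missed the threshold when its probes were averaged (adjusted p = 0.0586). Of 17 basement membrane genes 5 fell and 0 rose (adjusted over the list alone, 6 and 0; adjusted p = 0.00325, or adjusted p = 0.21 with an estimated correlation), among them the nidogen gene NID2, 1.45-fold, and the laminin gene LAMB1, 1.49-fold.

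Of 31 interferon response genes 6 fell in the RWV on collagen I and 0 rose (adjusted over the list alone, 8 and 0; adjusted p = 0.000486, or adjusted p = 0.467 with an estimated correlation), with the interferon signalling factor STAT2 down 1.44-fold and IFI27 1.70-fold. Of 25 inflammatory cytokine genes 6 fell and 1 rose (adjusted over the list alone, 6 and 1; adjusted p = 0.0143, or adjusted p = 0.21 with an estimated correlation). The chemokine gene CCL2 fell 2.05-fold and IL1B 1.87-fold, to a level detected on 1 of 3 arrays, and PTGES, a prostaglandin E synthase, rose 1.49-fold. IL6 fell by 0.53 on the log2 scale (adjusted p = 0.00713), FN1 by 0.66 (adjusted p = 0.00838), PPARG by 0.56 (adjusted p = 0.00152) and SOX9, a chondrocyte transcription factor, by 0.72 (adjusted p = 0.00101). COL6A3 fell by 0.35 (adjusted p = 0.0169), and its adjusted p was 0.0652 without RWV collagen I array 3, 0.0597 without monolayer collagen I array 1 and 0.0508 with the normexp correction. TNFRSF11B rose by 0.50 (adjusted p = 0.0125). The osteogenic genes RUNX2 (−0.10), ALPL (−0.07), BGLAP (−0.01) and SPP1 (−0.27) missed the threshold, with adjusted p values of 0.426, 0.833, 0.947 and 0.0549, and BMP2 was undetected in both. SPP1 passed without RWV hMatrix array 3 (adjusted p = 0.0329) or monolayer hMatrix array 2 (adjusted p = 0.048), and with the normexp correction (log2 change −0.63, adjusted p = 0.0212). DKK1 (−0.41, adjusted p = 0.0501) passed without monolayer hMatrix array 1 (adjusted p = 0.0135) or 2 (adjusted p = 0.0171). COL1A1 (−0.06), COL12A1 (0.18), POSTN (−0.33), VEGFA (−0.30), CXCL12 (−0.18), ACTA2 (0.17) and CCN2 (0.15) had adjusted p values between 0.103 and 0.528, and the other 2 of the 3 probes of CXCL12 passed as lower in the RWV. Of the 2 probes of POSTN, 1 also passed as lower there.

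On collagen I, 901 genes were higher and 743 lower in the RWV than in monolayer, 12.7% of those tested, with 19 and 10 of them changed at least 2-fold (112 and 42 with the normexp correction). With that correction IL1B fell 4.15-fold, IFI44L 3.74-fold and ANXA10 3.41-fold, more than ITGA2 (3.18-fold). The counts were 518 and 386 without RWV collagen I array 1, 498 and 380 without array 2, 585 and 442 without monolayer collagen I array 1, and 527 and 469 without array 3. Without RWV collagen I array 3 the count of lower genes was 477. Of 32 lists, 8 passed.

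The fourth comparison set the RWV against monolayer on hMatrix. TXNIP had the largest rise in the RWV, 7.33-fold, from 447.2 ± 193 to 3064 ± 608 units (log2 change 2.87, SE 0.27, adjusted p = 2.75e-05). BEX1 (chromosome X), a brain-expressed gene, rose 4.21-fold (adjusted p = 4.83e-08, passed by 1 of its 2 probes), CDC20 2.98-fold, PRRX2 (chromosome 9), a mesenchymal homeobox gene, 2.88-fold and KRT81 2.84-fold. LBP (chromosome 20), which encodes lipopolysaccharide-binding protein, rose 2.83-fold from a level detected on 2 of 3 monolayer arrays. PSAT1 (chromosome 9) showed the largest fall, 3.69-fold, from 2181 ± 190 to 602.4 ± 153 units (log2 change −1.88, SE 0.14, adjusted p = 5.63e-06). CCL2 (chromosome 17) fell 3.24-fold, MME (chromosome 3), the endopeptidase neprilysin, 2.51-fold, and TRIB3 (chromosome 20), a pseudokinase gene induced by ATF4, 2.48-fold. MTHFD2 (chromosome 2), a mitochondrial folate enzyme, fell 2.44-fold and ASNS (chromosome 7), asparagine synthetase, 2.33-fold.

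The amino acid genes among these belong to the unfolded protein and amino acid response, of which 14 of 27 members fell and 6 rose in the RWV on hMatrix (adjusted over the list alone, 16 and 6; adjusted p = 6.37e-05, or adjusted p = 0.18 with an estimated correlation). The chaperone gene HSP90B1 rose 1.87-fold and SDF2L1, also of the endoplasmic reticulum, 1.40-fold. Cell cycle genes rose in 21 of 29 cases and fell in 0 (adjusted over the list alone, 23 and 0; adjusted p = 3.81e-18, or adjusted p = 0.0548 with an estimated correlation), with TK1 up 2.02-fold and BIRC5, survivin, 1.9-fold. MKI67 was undetected in both. Of 23 genes of cholesterol synthesis 10 rose and 0 fell (adjusted over the list alone, 11 and 0; adjusted p = 3.68e-05, or adjusted p = 0.177 with an estimated correlation), including the farnesyl diphosphate synthase gene FDPS, 1.36-fold. Of 22 genes of oxidative and metal stress 11 rose and 2 fell (adjusted over the list alone, 12 and 5; adjusted p = 0.0218, or adjusted p = 0.277 with an estimated correlation), a call lost without monolayer hMatrix array 3 (adjusted p = 0.0679). The metallothionein gene MT1X rose 1.67-fold and GCLM, of glutathione synthesis, fell 1.41-fold.

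POSTN fell by 0.94 on the log2 scale in the RWV on hMatrix (adjusted p = 0.000436), IL6 by 0.66 (adjusted p = 0.0016), and COL12A1 rose by 0.64 (adjusted p = 0.00664). The calls of 3 genes with smaller changes were lost without 1 array. COL1A1 rose by 0.21 (adjusted p = 0.0304), with adjusted p values of 0.0549, 0.0849 and 0.0875 without RWV hMatrix arrays 1, 2 and 3, 0.0939 and 0.0717 without monolayer hMatrix arrays 2 and 3, and 0.132 with the normexp correction. TNFRSF11B fell by 0.44 (adjusted p = 0.0193), with 0.0519 and 0.07 without RWV hMatrix arrays 2 and 3 and 0.0764 without monolayer hMatrix array 2. CCN2 fell by 0.37 (adjusted p = 0.0234), with 0.0592 and 0.0821 without RWV hMatrix arrays 1 and 3, 0.0709 and 0.0888 without monolayer hMatrix arrays 2 and 3, and 0.0509 with the normexp correction. Missing the threshold were RUNX2 (0.02), ALPL (0.20), BGLAP (0.09), BMP2 (0.05), COL3A1 (0.22), COL6A3 (0.09), FN1 (−0.26), DKK1 (−0.06), PPARG (−0.08), VEGFA (0.23), SOX9 (−0.16) and ACTA2 (0.00), with adjusted p values between 0.14 and 0.989. SPP1 (−0.26, adjusted p = 0.0535) passed without RWV hMatrix array 1 (adjusted p = 0.0421), monolayer hMatrix array 1 (adjusted p = 0.0434) or monolayer collagen I array 3 (adjusted p = 0.0449). CXCL12 had a log2 change of 0.01 (adjusted p = 0.94), and its other 2 probes passed with lower values in the RWV. Of the 3 probes of FN1, 1 passed as lower in the RWV.

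On hMatrix, 1282 genes were higher and 919 lower in the RWV than in monolayer, 17% of those tested, with 25 and 14 of them changed at least 2-fold (117 and 43 with the normexp correction). The counts were 849 and 567 without RWV hMatrix array 1, 726 and 528 without array 2, 839 and 584 without array 3, and 745 and 583 without monolayer hMatrix array 2. Of 32 lists, 5 passed. Effects of the culture system on the 2 coatings had a correlation of 0.444 across genes, which are not independent replicates, with 360 genes higher on both coatings (89.4 expected if they were independent), 163 lower on both (52.8 expected) and 62 called in opposite directions (138 expected). Both comparisons use the same estimate of the spread per gene, so a gene of small spread passes more readily in both. Anything that all monolayer arrays share would also enter both. The expected counts leave this out.

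**Figure D3:**
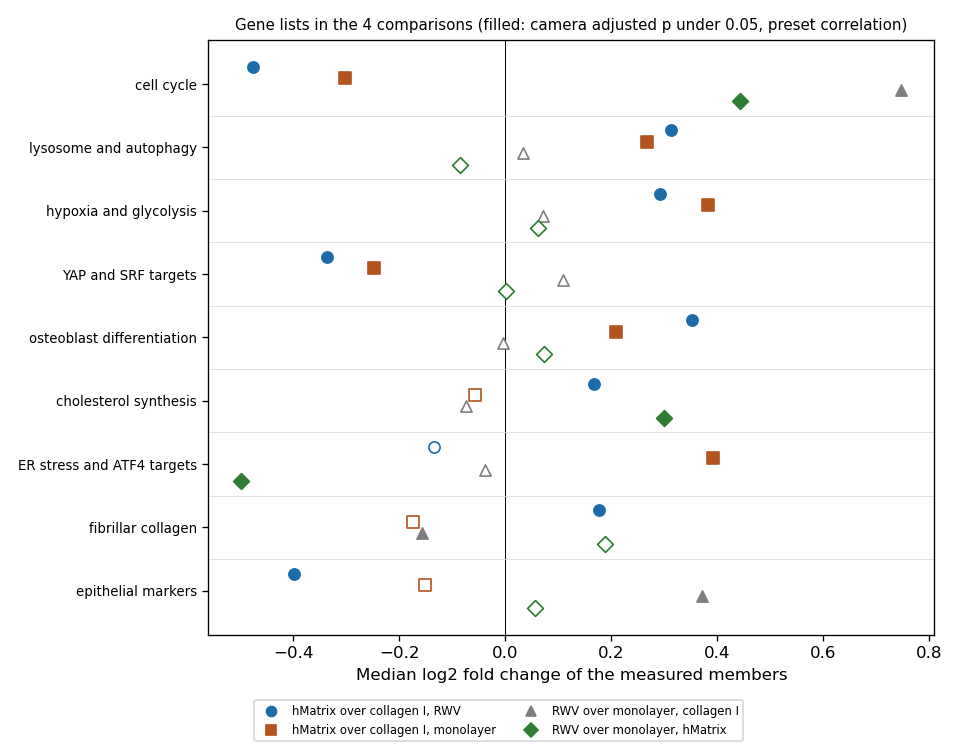
Median log2 change of the measured genes of 9 lists in the 4 comparisons of 2 groups, with 1 marker per comparison, filled where camera gave an adjusted p under 0.05. Cell cycle genes lie below 0 in both comparisons of coatings and above 0 in both comparisons of culture systems.

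The interaction asked whether hMatrix changed a gene by a different amount in the RWV than in monolayer. Coating effects in the RWV and in monolayer had a correlation of 0.685 across genes, which are not independent replicates. Both comparisons called 789 genes higher (204 expected if they were independent) and 938 lower (237 expected), while 70 were called in opposite directions (440 expected). The expected counts leave out that both comparisons use the same estimate of the spread per gene. LXN (chromosome 3), a carboxypeptidase inhibitor, rose on hMatrix in the RWV by 1.71 on the log2 scale (adjusted p = 6.19e-09) and had a log2 change of −0.15 in monolayer (adjusted p = 0.179), a difference of 1.86 (SE 0.11, adjusted p = 1.6e-06). BEX1 rose by 0.53 in the RWV and fell by 1.41 in monolayer (difference 1.94, SE 0.13, adjusted p = 6.65e-06). LYPD1 (chromosome 2) differed by 1.78, RARRES1 (chromosome 3), a retinoic acid receptor responder, by 1.64, and LBP, undetected in both collagen I groups, by 1.51, a value that contains background. CRIP1 rose by 1.88 in monolayer and changed by 0.05 in the RWV (difference −1.82, SE 0.25, adjusted p = 0.00112). PSAT1 fell by 0.64 in the RWV and rose by 1.04 in monolayer (difference −1.67, SE 0.20, adjusted p = 0.000376). KRT14 was detected in the RWV on collagen I and in none of the other 3 groups, so its difference of −1.67 contains background. KRT7 fell by 1.82 in the RWV and had a log2 change of −0.24 in monolayer (adjusted p = 0.122; difference −1.58). EFHD1 (chromosome 2) fell by 1.84 in the RWV and by 0.26 in monolayer (difference −1.58).

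A higher effect means a higher log2 change on hMatrix in the RWV, through a larger rise or a smaller fall. It was higher for 7 of 23 genes of cholesterol synthesis and lower for 0 (adjusted over the list alone, 11 and 0; adjusted p = 1.17e-06, or adjusted p = 0.132 with an estimated correlation). The squalene synthase gene FDFT1 differed by 0.53 (adjusted p = 0.0108, or 0.109 when its probes were averaged). The effect of hMatrix was higher for 7 of 24 fibrillar collagen and processing genes and lower for 1 (adjusted over the list alone, 12 and 1; adjusted p = 3.57e-05, or adjusted p = 0.132 with an estimated correlation), with the lysyl oxidase gene LOXL3 at 0.86, COL3A1 at 0.75 and COL11A1 at −1.19. Among basement membrane genes it was higher for 4 of 17 and lower for 0 (adjusted over the list alone, 6 and 0; adjusted p = 7.98e-05, or adjusted p = 0.142 with an estimated correlation), with the laminin gene LAMA4 at 0.98 and NID2 at 0.90. Of these 17, 8 had fallen in monolayer and 3 in the RWV. ITGA2 differed by 1.16, and 3 of 23 integrin genes were higher and 0 lower (adjusted over the list alone, 3 and 0; adjusted p = 0.00977, or adjusted p = 0.161 with an estimated correlation). The effect was lower for 11 of 27 genes of the unfolded protein and amino acid response and higher for 2 (adjusted over the list alone, 15 and 5; adjusted p = 9.83e-05, or adjusted p = 0.18 with an estimated correlation), with the mitochondrial phosphoenolpyruvate carboxykinase gene PCK2 at −1.14 and HSP90B1 at 0.88. Of 7 epithelial markers it was lower for 2 and higher for 0 (adjusted over the list alone, 2 and 0; adjusted p = 0.00118, or adjusted p = 0.0813 with an estimated correlation).

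Of the focus genes, COL3A1 (0.75, adjusted p = 0.00945) and TNFRSF11B (−0.93, adjusted p = 0.00539) passed in the interaction. PPARG (0.48, adjusted p = 0.0537) passed without RWV collagen I array 2 (adjusted p = 0.0484) or monolayer collagen I array 3 (adjusted p = 0.0327), and CCN2 (−0.52, adjusted p = 0.0571) without monolayer hMatrix array 1 (adjusted p = 0.0185). COL6A3 (0.43, adjusted p = 0.0567) passed without monolayer hMatrix array 2 (adjusted p = 0.0303) or monolayer collagen I array 3 (adjusted p = 0.0325), FN1 (0.39, adjusted p = 0.31) without monolayer hMatrix array 2 (adjusted p = 0.0448), and POSTN (−0.62, adjusted p = 0.0698) without monolayer collagen I array 3 (adjusted p = 0.0118). Of the 2 probes of COL6A3, 1 passed with a higher effect in the RWV. RUNX2 (0.13), ALPL (0.27), SPP1 (0.01), BGLAP (0.10), BMP2 (−0.02), COL1A1 (0.27), COL12A1 (0.46), DKK1 (0.35), VEGFA (0.53), IL6 (−0.14), CXCL12 (0.20), SOX9 (0.56) and ACTA2 (−0.16) missed the threshold, with adjusted p values between 0.0639 and 0.981. MKI67, undetected in 3 of the 4 groups, had a difference of −0.19 that contains background (adjusted p = 0.253), and passed with the normexp correction (adjusted p = 0.0176).

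The effect of hMatrix was higher in the RWV than in monolayer for 292 genes and lower for 245, 4.16% of those tested, and 25 and 33 of them differed at least 2-fold (92 and 112 with the normexp correction). The counts were 177 and 156 without RWV hMatrix array 1, 168 and 153 without RWV hMatrix array 2, 168 and 160 without RWV collagen I array 1, 174 and 145 without RWV collagen I array 3, and 177 and 156 without monolayer collagen I array 1. Without monolayer hMatrix array 3 the count of higher effects was 179. With array weights the counts were 454 and 387. Of 32 lists, 12 passed.

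**Figure D4:**
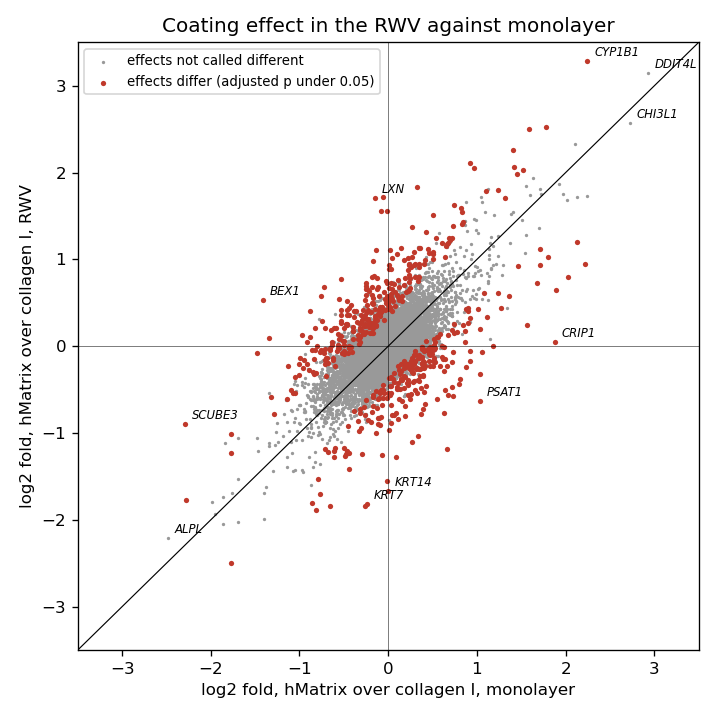
Log2 change on hMatrix over collagen I in the RWV (y axis) against that in monolayer (x axis), with 1 point per gene and genes past the threshold of the interaction in red. Most points lie along the diagonal (correlation 0.685 across 12924 genes), and the 537 red points lie off it.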

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

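Chosen only after the results were seen were both tests on keratin genes, the test of signal quality, the removal of the GC trend, the normexp correction, and the look at relabellings that place the coatings equally. A difference between the coating's effect in the RWV and in monolayer brought up 292 genes with a higher and 245 with a lower effect in the RWV. Among genes named in the text, the log2 effect of hMatrix was higher in the RWV by 1.94 for BEX1, 1.86 for LXN, 1.78 for LYPD1, 1.64 for RARRES1, 1.51 for LBP, 1.40 for LRRC17, 1.39 for SCUBE3, 1.31 for ANXA10, 1.16 for ITGA2, 1.09 for SCD, 1.04 for CYP1B1, 0.98 for LAMA4, 0.92 for COLEC12 and 0.90 for NID2. Smaller positive differences were those of HSP90B1 (0.88), INSIG1 (0.88), DLX5 (0.86), LOXL3 (0.86), CTSZ (0.83), COL3A1 (0.75), HAS3 (0.74), ID2 (0.68), MGP (0.66), TGFB3 (0.66), SDC1 (0.64), ADAMTS5 (0.62), LAMC1 (0.61), IL1B (0.55), FDFT1 (0.53) and P3H2 (0.51). The effect was lower in the RWV for CRIP1 (−1.82), PSAT1 (−1.67), KRT14 (−1.67), KRT7 (−1.58), EFHD1 (−1.58), KRT34 (−1.40), MME (−1.31), RGCC (−1.27), CTSK (−1.23), TRIB3 (−1.23), COL11A1 (−1.19), ASNS (−1.18), CNN1 (−1.18), MTHFD2 (−1.15), PCK2 (−1.14), DBNDD2 (−1.08) and KRT81 (−1.07). Smaller negative differences were those of FST (−0.99), PTGDS (−0.93), TNFRSF11B (−0.93), IGFBP5 (−0.79), COMP (−0.78), ANKRD1 (−0.78), IGFBP2 (−0.72), KRT16 (−0.66), CCL2 (−0.66), PSPH (−0.60) and KRT17 (−0.43). All these differences contain background. Those of LBP, KRT14 and KRT16 do so most plainly, since 2, 3 and 2 of their 4 groups were undetected, as do those of ADAMTS5 and IL1B, each detected on 1 of 3 RWV collagen I arrays. With the normexp correction KRT16 differed by −2.05, COL11A1 by −2.545, NID2 by 1.86 and ANXA10 by 2.07, so the order of sizes changed.

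Of these 58 genes, 47 passed whichever array was left out, and 11 did not. The highest adjusted p of these was 0.104 for CCL2 without monolayer hMatrix array 3, 0.117 for P3H2 without RWV collagen I array 3, 0.113 for PSPH without RWV hMatrix array 2, 0.0901 for SDC1 without RWV collagen I array 3, 0.0786 for ANKRD1 without monolayer hMatrix array 3, 0.0872 for HAS3 without RWV collagen I array 1, 0.11 for IL1B without RWV hMatrix array 2, 0.103 for LAMC1 without RWV hMatrix array 2, 0.0653 for KRT17 without RWV hMatrix array 1, 0.0575 for DLX5 without RWV collagen I array 3 and 0.0521 for ADAMTS5 without RWV collagen I array 1. With the normexp correction the adjusted p was 0.0573 for CCL2, 0.0791 for P3H2, 0.0718 for PSPH, 0.0822 for SDC1, 0.0925 for HAS3, 0.0995 for IL1B and 0.081 for LAMC1.

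Probes outside the gene tests were fitted and adjusted on their own. Of the probes without a gene symbol 518 were measured, of which 79 and 76 passed between coatings in the RWV and in monolayer, 20 and 25 between culture systems on collagen I and on hMatrix, and 4 in the interaction. Each is a smaller share than among genes, where 25.1%, 27.1%, 12.7%, 17% and 4.16% passed in the same order.

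In each comparison of 2 groups, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each: 3247 between coatings in the RWV (highest other 0), 3506 in monolayer (highest other 0), 1644 between culture systems on collagen I (highest other 0) and 2201 on hMatrix (highest other 1). Every other split put arrays of both groups under each label, so the real difference widened the spread within groups. Their low counts were close to fixed in advance, and these splits say nothing about chance. For the interaction, 7 of 100 drawn relabellings of coating gave at least the real 537 genes, the highest other giving 4929, so this test did not exclude chance. The other 6 all gave the hMatrix label to unequal numbers of hMatrix arrays in the RWV and in monolayer and so carried the coating's own effect, a structure of the samples. Among the 48 other draws with equal placement the highest count was 0. Each of these draws put both coatings under the same label, so the coating's own effect widened the spread within groups. A count near 0 was therefore close to fixed in advance and says nothing about chance.

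The first pattern is that of keratin genes. Of 11 measured, 8 fell on hMatrix in the RWV and 8 rose in the RWV over monolayer on collagen I. A large share of epithelial cells in the cultures is argued against by their other markers, of which 2 of 13 (MUC1 and ELF3) were detected on all 3 RWV collagen I arrays. A small share is not excluded. KRT14 was itself dim there (355.6 ± 2.94 units), and a few cells could leave the other markers undetected. A single transcript read by all keratin probes is argued against by monolayer, where KRT17, KRT34 and KRT81 rose on hMatrix while 3 fell. No other explanation was tested, and KRT81 and KRT19 also rose in the RWV over monolayer on hMatrix.

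The second pattern is that monolayer hMatrix array 2 and monolayer collagen I array 3 deviated from their groups together. The correlation of deviations was 0.58 across genes (0.53 for hMatrix array 1 with collagen I array 2, and 0.26 for hMatrix array 3 with collagen I array 1). PRRX2 (−0.56 and −0.65) and IFI6 (−0.82 and −0.90) lay below their group and CDC42BPB, PPDPF and NACC1 above. The interferon response list, which holds IFI6, did not deviate together. Its median deviation was 0.424 on the first array and −0.0744 on the second. A shared difference in growth state is argued against by 29 cell cycle genes, whose median deviations had opposite signs, −0.0971 (23 genes below their group) and 0.0307 (9 genes below). Their SE from a bootstrap over genes, which are not independent replicates, were 0.0287 and 0.0212. These SE do not measure the spread between cultures. High-minus-low GC differences were alike within these pairs (−0.0326 and −0.0421, 0.0674 and 0.0768, −0.0348 and −0.0347, in that order), but a trend with GC content as the whole cause is argued against by a correlation of 0.574 after its removal. Signal quality stays open, as both arrays were at the same end of their groups at 1 of 2 detection thresholds: most probes detected at 0.01 (17784 and 18202), and the most (21479) and the fewest (20897) at 0.05. A shared slide or culture day was not tested, as neither is given.

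The third pattern is TXNIP, higher in the RWV on both coatings, with the ATF4 targets PSAT1, TRIB3, MTHFD2 and ASNS lower in the RWV on hMatrix. ATF4 targets were not tested as a list of their own. The unfolded protein and amino acid response list, which holds them, did not pass with an estimated correlation. A general fall of the endoplasmic reticulum stress response is argued against by 9 of its genes, most of them chaperones or folding enzymes. Of these 6 rose and 1 fell, with a median log2 change of 0.368. The fallen gene, HERPUD1, is not a chaperone. The other 18 measured members of that list had a median of −0.618, with 13 fallen and 0 risen. Glucose at harvest may differ between culture systems and stays open, since ARRDC4, the other glucose-responsive arrestin gene, had log2 changes of 0.20 on collagen I (adjusted p = 0.194) and 0.2591 on hMatrix (adjusted p = 0.0789). Other biological explanations were not tested.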

How the results depend on the processing

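The normexp background correction and the fit without monolayer hMatrix array 2 and monolayer collagen I array 3 were chosen after the data were seen, as was the estimated correlation with arrays left out. Of 296 counts under alternatives, 237 stayed within 1.5 times the reported count and 59 did not. These include the floor of 1, the deposited series values and a repeated quantile normalization, which could hardly move a count. No value lay under 16, the series values were the same, and the arrays already shared one distribution. Array weights gave 454 higher and 387 lower effects in the interaction. Fitting only the arrays compared gave 1098 genes higher on hMatrix in monolayer. The other movements came from stricter calling rules, which by construction call fewer genes, or from leaving out arrays. Except for the stricter rules, the cause was not tested.

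The rule of the series design text, which cannot be applied to the interaction, called 104 higher and 78 lower genes on hMatrix in the RWV, 81 and 56 in monolayer, 19 and 10 in the RWV over monolayer on collagen I, and 20 and 13 on hMatrix. A 2-fold minimum beside the adjusted p gave 111 and 80, 88 and 65, 19 and 10, and 25 and 14 in the same order, with 25 and 33 in the interaction. An adjusted p under 0.01 gave 915 and 924, 857 and 1046, 377 and 256, 507 and 318, and 88 and 87.

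Leaving out each array in turn gave 1114 to 1696 higher and 1125 to 1761 lower genes on hMatrix in the RWV, 1204 to 1616 and 1438 to 1811 in monolayer, 498 to 1080 and 380 to 902 in the RWV over monolayer on collagen I, 726 to 1440 and 528 to 1035 on hMatrix, and 168 to 351 and 145 to 274 in the interaction. Without monolayer hMatrix array 2 and monolayer collagen I array 3, the counts were 1855 and 1915, 1318 and 1603, 714 and 635, 959 and 711, and 364 and 278.

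Of the results for named genes under alternatives, 10056 kept their direction and side of the threshold, 253 lost the threshold, 112 gained it and 1 reversed. The floor of 1, the series values and the repeated quantile normalization each kept all 393 gene results and all 160 list results, close to by construction. CXCL12 was lower in the RWV on hMatrix by 0.38 (log2 change −0.38, adjusted p = 0.00419) when its probes were averaged, since its other 2 probes were lower there. Of the results for lists 4253 kept both, 112 lost the threshold and 86 gained it, and 51 of the 112 came with an estimated correlation. No paired analysis was possible because the replicate numbers only give the order of deposition. A block for the slide was not run, since no slide is named.

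Signal over background limits the dim genes. Undetected probes lie near 113 units, so a gene at 150 units is mostly background, and its fold is understated. With the normexp correction ALPL on hMatrix fell by 2.63 in the RWV and by 3.03 in monolayer, against 2.21 and 2.48 as deposited, and KRT81 in the RWV on collagen I rose by 3.70 against 2.58. COL1A1 lies near the ceiling, where changes are compressed.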

Other observations

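The fit without monolayer hMatrix array 2 and monolayer collagen I array 3, the normexp correction, and the estimated correlation with arrays left out, whose values appear here, were chosen after the results were seen. Further lists passed on hMatrix in the RWV. Of 23 genes of p53 signalling and senescence 11 rose and 4 fell (adjusted over the list alone, 13 and 5; adjusted p = 0.0114, or adjusted p = 0.18 with an estimated correlation), with GDF15 up by 1.72 and GLB1, the senescence-associated galactosidase gene, by 0.90 on the log2 scale, and IGFBP5 and IGFBP3, binding proteins of insulin-like growth factors, down by 0.90 and 0.88. Of 13 adipogenic genes 6 rose and 1 fell (adjusted over the list alone, 7 and 2; adjusted p = 0.00312, or adjusted p = 0.132 with an estimated correlation), including the stearoyl desaturase gene SCD by 1.11 and the apolipoprotein gene APOE at least 1.45-fold. Of 23 genes of cholesterol synthesis 9 rose and 1 fell (adjusted over the list alone, 11 and 1; adjusted p = 0.0067, or adjusted p = 0.298 with an estimated correlation), with the sterol sensor gene INSIG1 up by 1.31. Of 18 matrix protease and inhibitor genes 8 rose and 1 fell (adjusted over the list alone, 9 and 1; adjusted p = 0.0125, or adjusted p = 0.132 with an estimated correlation), with the aggrecanase gene ADAMTS5 up by 1.07, from a level detected on 1 of 3 arrays, and MMP11 by 0.85. That call was lost among genes detected on all 12 arrays (adjusted p = 0.0556).

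The other calls in the RWV were less stable. Of 22 genes of oxidative and metal stress 9 rose and 3 fell on hMatrix (adjusted over the list alone, 9 and 5; adjusted p = 0.0361, or adjusted p = 0.298 with an estimated correlation), with AKR1C2, an aldo-keto reductase, up by 1.46, and the call was lost without monolayer collagen I array 1 (adjusted p = 0.0587). Of 24 fibrillar collagen and processing genes 9 rose and 3 fell (adjusted over the list alone, 9 and 3; adjusted p = 0.0399, or adjusted p = 0.298 with an estimated correlation), with CRTAP, of collagen hydroxylation, up by 0.76, and P3H2 and the lysyl oxidase gene LOXL4 down by 1.77 and 1.28. This call was lost without RWV hMatrix array 1 (adjusted p = 0.0981) or 2 (adjusted p = 0.0643) and without RWV collagen I array 1 (adjusted p = 0.0587) or 2 (adjusted p = 0.0601), and with the normexp correction (adjusted p = 0.0934).

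On hMatrix in monolayer, 11 of 23 genes of p53 signalling and senescence rose and 2 fell (adjusted over the list alone, 12 and 2; adjusted p = 0.00578, or adjusted p = 0.169 with an estimated correlation), with the antiproliferative gene BTG2 up by 1.02 and IGFBP3 down by 1.06. Of 18 protease and inhibitor genes 7 rose and 2 fell (adjusted over the list alone, 7 and 2; adjusted p = 0.0114, or adjusted p = 0.132 with an estimated correlation), with the collagen-degrading cathepsin gene CTSK up by 2.03 and the urokinase gene PLAU by 1.13. The adjusted p was 0.0522 without monolayer hMatrix array 2 and monolayer collagen I array 3. Of 29 ribosomal protein genes 6 rose and 0 fell (adjusted over the list alone, 5 and 0; adjusted p = 0.00578, or adjusted p = 0.21 with an estimated correlation). Of 8 chondrogenic genes 4 rose and 1 fell (adjusted over the list alone, 5 and 2; adjusted p = 0.0442, or adjusted p = 0.21 with an estimated correlation), with COMP, a cartilage matrix protein, up by 1.71 and the growth factor gene GDF5 down by 0.57. The chondrogenic call was lost without RWV hMatrix array 1 (adjusted p = 0.0537), monolayer hMatrix array 2 (adjusted p = 0.0569) or monolayer collagen I array 1 (adjusted p = 0.0587) or 2 (adjusted p = 0.0736).

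Of 31 interferon response genes 9 fell on hMatrix in monolayer and 0 rose (adjusted over the list alone, 9 and 1; adjusted p = 0.00932, or adjusted p = 0.591 with an estimated correlation), with IFI27 down by 1.25 and BST2, tetherin, by 0.76. Monolayer hMatrix array 2 lay above the other 2 on this list, with a median deviation of 0.424 against −0.259 and −0.173. The call was lost without monolayer hMatrix array 1 (adjusted p = 0.12) or 3 (adjusted p = 0.089). In the interaction the list had adjusted p = 0.166, or adjusted p = 0.82 with an estimated correlation. With the preset correlation it passed without monolayer hMatrix array 2 (adjusted p = 4.5e-09) and without that array and monolayer collagen I array 3 (adjusted p = 6.95e-11), and with an estimated correlation it did not (adjusted p = 0.115 and 0.0686).

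Between the RWV and monolayer on collagen I, 2 of 10 smooth muscle and pericyte markers rose and 0 fell (adjusted over the list alone, 2 and 0; adjusted p = 0.0159, or adjusted p = 0.142 with an estimated correlation), CNN1 by 0.74 and MCAM by 0.54. Of 29 ribosomal protein genes 3 rose and 0 fell (adjusted over the list alone, 3 and 0; adjusted p = 0.0148, or adjusted p = 0.256 with an estimated correlation), and the call was lost without monolayer collagen I array 1 (adjusted p = 0.0589). On hMatrix, 4 of 16 heat shock genes rose in the RWV and 0 fell (adjusted over the list alone, 5 and 0; adjusted p = 0.0458, or adjusted p = 0.309 with an estimated correlation), with HSPA1B up by 0.63. That call was lost without monolayer hMatrix array 1 (adjusted p = 0.129) or 3 (adjusted p = 0.0846), RWV hMatrix array 1 (adjusted p = 0.121) or monolayer collagen I array 3 (adjusted p = 0.0543), and with the normexp correction (adjusted p = 0.103).

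In the interaction, the list of cell cycle genes passed with 0 members past the threshold (adjusted p = 0.00719, or adjusted p = 0.298 with an estimated correlation), and after subtraction of the lowest value of each array its adjusted p was 0.455, and with the normexp correction 0.478. The adipogenic list passed (adjusted p = 0.0168, or adjusted p = 0.169 with an estimated correlation) with SCD at 1.09, and the immediate early list passed with 2 genes lower and 0 higher (adjusted over the list alone, 8 and 0; adjusted p = 0.0036, or adjusted p = 0.18 with an estimated correlation). The smooth muscle list (adjusted p = 0.0472, or adjusted p = 0.18 with an estimated correlation) was lost without RWV hMatrix array 1 (adjusted p = 0.0522) or 3 (adjusted p = 0.0799), RWV collagen I array 2 (adjusted p = 0.0555) or 3 (adjusted p = 0.0632), monolayer hMatrix array 1 (adjusted p = 0.106) or monolayer collagen I array 3 (adjusted p = 0.114), and CNN1 differed by −1.18. The heat shock list had adjusted p = 0.0131, or adjusted p = 0.256 with an estimated correlation. The ribosomal list (adjusted p = 0.0279, or adjusted p = 0.292 with an estimated correlation) was lost without RWV hMatrix array 1 (adjusted p = 0.127), monolayer hMatrix array 3 (adjusted p = 0.0556) or monolayer collagen I array 1 (adjusted p = 0.0646), and with the normexp correction (adjusted p = 0.0548).

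Markers of macrophages and blood cells passed in none of the contrasts, with adjusted p values of 0.779 and 0.641 between coatings in the RWV and in monolayer, 0.0991 and 0.232 between culture systems on collagen I and on hMatrix, and 0.857 in the interaction. On collagen I the list passed without monolayer collagen I array 2 with the preset correlation (adjusted p = 0.0321) and missed with an estimated one (adjusted p = 0.272).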
